A study of Homo sapiens with 12 samples.

How the data were processed

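RNA sequencing was analysed from 12 libraries of hCMEC/D3, an immortalised human brain microvascular endothelial cell line that is used as a culture model of the blood-brain barrier. Per the labels, 4 libraries came from untreated cells, 4 from cells given particles of 35 nm and 4 from cells given particles of 58 nm, each at 100 µg/mL for 24 h. The labels call the particles SiNPs, which are taken here to be silica nanoparticles. They do not say whether the controls received a vehicle, nor whether the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, cells were lysed in a detergent buffer, RNA was purified with a column kit and libraries followed a standard Illumina protocol. Whether polyadenylated RNA was selected and whether the libraries kept strand information is not given in the sources used here.

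The authors deposited 1 table with an FPKM value (fragments per kilobase of gene length, scaled to the size of the library) for 58735 genes in each library. The gene length beside each value is part of the deposited table, per the file headers. Per the submitters' processing notes, the aligner was Bowtie 0.12.2 and the build was hg19. The table itself does not carry that build: the identifier, chromosome, start, end and exon-union length of 58735 of 58735 genes equalled those of GENCODE 29, which is an annotation of GRCh38. Coordinates are therefore given as the deposited table has them, in GRCh38, and the alignment build stays unresolved. The counting tool and the treatment of reads with several alignments are not given in the sources used here. In it, 27 gene names had been turned into dates, and these were named again through their gene identifiers.

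Multiplying each FPKM value by its gene length gave whole multiples of 1 read for 100% of values in each library, within a tolerance of 0.01 reads. The recovered gene reads ranged from 9472317 to 10678269 per library, so depth differed little between libraries. The library sizes that the authors divided by ranged from 9597535 to 10933782, which is 99.7% to 102.7% of the gene reads. A count of 3 reads in a gene of 1 kb corresponded to 0.274 to 0.313 FPKM. Intervals on shares of reads are exact Clopper-Pearson intervals at the 95% level and cover counting error, not the spread between cultures.

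Values were tested on the scale log2(FPKM + 1), so the pseudocount was 1 and fold changes of low genes are understated. Genes with a mean of at least 1 FPKM over the 12 libraries were kept, which left 12176 genes; 29099 genes were at 0 in every library. A model of 3 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (trended and robust prior), because the groups then share 1 estimate of the spread. The comparisons made were 35 nm against control, 58 nm against control and 58 nm against 35 nm. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison. A gene is said to have risen or fallen where its adjusted p was under 0.05.

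Before the data were examined, 36 gene lists were fixed, of which 34 had at least 5 tested members. They cover junctions, transporters and receptors of the blood-brain barrier, endothelial identity, NF-kB and interferon responses, oxidative, unfolded protein and heat stress, cholesterol synthesis, lysosomes, autophagy, p53, cell cycle, apoptosis, metallothioneins, respiration, glycolysis, matrix and its proteases, TGF-beta signalling, YAP, SRF and actin, iron and ferroptosis, inflammasomes, endocytosis, immediate early genes, coagulation, angiogenesis, ribosomal proteins, replication histones and mitochondrially encoded genes, with markers of 5 other cell types. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. With an estimated correlation, 0 lists stayed under an adjusted p of 0.05 in either comparison with control and 2 did so in 58 nm against 35 nm, so both p-values are given beside list results. Counts adjusted over the list alone use the adjustment within that list.

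The genes named were set by a rule fixed beforehand: in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 FPKM and fully separated groups, the 3 members with the smallest p of the 6 lists with the smallest p, and a panel of 24 genes. Further genes were chosen after their values were seen, to describe list members. These are TNC, TFRC, ACO1, CXCL10, TXNIP, IFIT2, ISG15, FTH1, SDF2L1, FKBP4, HSPE1, SLC16A3, TNFAIP3, NFKBIA, RELB, CXCL6, MT-CO1, MT-ND3, JUNB, MFSD2A, COL4A1, TIMP2, TIMP3, TAGLN, ID2, SOX9, HLA-B, B2M, NLRC5, IFNB1, IFNE, the cell type markers given under other observations and, in comparisons other than the one where the rule named it, any gene of the rule. Some genes that the rule selected are not reported here. Further lists of 15 MHC class I genes, 4 interferon receptor and kinase genes and 15 genes of mitochondrial transcription were written after the data were seen but before their own values were.

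The procedure was tested on simulated data. In simulated reads for 12327 genes of the comparison of 35 nm with control, 26 of 50 genes changed 1.25-fold, 41 of 49 changed 1.5-fold, 48 of 50 changed 2-fold and 49 of 50 changed 4-fold were recovered, and 8 of 172 calls were false. The simulated reads were drawn independently, with the same dispersion (0.0036) for all genes, and held no trend with gene length or GC content. The share of false calls may therefore be higher in the data. Replicate libraries correlated at r = 0.979 to 0.984 across genes (genes are not independent replicates), and their mean chi-square per gene was 2.01 to 9.16, so no pair differed by as little as sampling noise.

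Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, upper-quartile rescaling, quantile normalization, limma without trend or robust prior, a fit of the 8 libraries compared, the replicate number as a block, leaving out each library in turn, a threshold on the size of the change, camera with an estimated correlation and fry. Added after seeing the data were removal of each library's trend with gene length and GC content (natural splines with 5 degrees of freedom, 12173 of 12176 genes having a GC value), removal of the length trend alone, limma-voom on the recovered reads, and limma array weights. Columns of other samples numbered 0, and no library was left out.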

Results

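RNA was sequenced from hCMEC/D3 brain endothelial cells that were left untreated or exposed to SiNPs of 35 nm or 58 nm, with 4 libraries in each of the 3 groups. The labels give 100 µg/mL and 24 h for both particle sizes. Gene reads numbered 10039422 to 10678269 per library in controls, 10039379 to 10469143 at 35 nm and 9472317 to 10466096 at 58 nm. The comparisons ask which transcripts differed in cells given either particle, and whether the responses to both sizes differed. Values are means ± SD of deposited FPKM with n = 4 libraries per group, and changes are log2 fold changes from limma on log2(FPKM + 1). Adjusted p-values are Benjamini-Hochberg values over 12176 genes. No label says that the libraries came from separate cultures, so these p-values may reflect technical spread only.

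All genes of the mitochondrial chromosome, its ribosomal and transfer RNA genes included, took up 3.12 ± 0.0558% of gene reads in controls, 1.89 ± 0.0597% at 35 nm and 2.89 ± 0.173% at 58 nm. The list of mitochondrially encoded transcripts used below holds the 13 that code for subunits of the respiratory chain and of ATP synthase. All 4 libraries at 35 nm lay below all 4 controls (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, adjusted p = 0.0644 over 9 tests). Between 58 nm and control the exact permutation p was 0.0571 (adjusted p = 0.0856). On the first principal component of the 12 libraries, which held 30.1% of the variance, controls lay at -17.15 to -11.49, 58 nm at -6.73 to 6.79 and 35 nm at 11.67 to 20.33. The second component, with 9.4%, set 58 nm (7.03 to 12.65) apart from the 8 other libraries (-8.64 to 1.07). The libraries also differed in how expression followed gene length and base composition. Spearman's rho across genes between expression relative to the other libraries and GC content averaged -0.36 ± 0.105 in controls, 0.33 ± 0.193 at 35 nm and -0.064 ± 0.293 at 58 nm (exact permutation p for 35 nm against control 0.0286, the smallest possible, adjusted p = 0.0644). Library 1 of the 58 nm group had a rho of -0.319 with gene length where the other 58 nm libraries had 0.09 to 0.164. Genes are not independent replicates, so these correlations describe the libraries. Where removal of both trends changed the call of a list, the adjusted p is given with it.

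**Figure D1:**
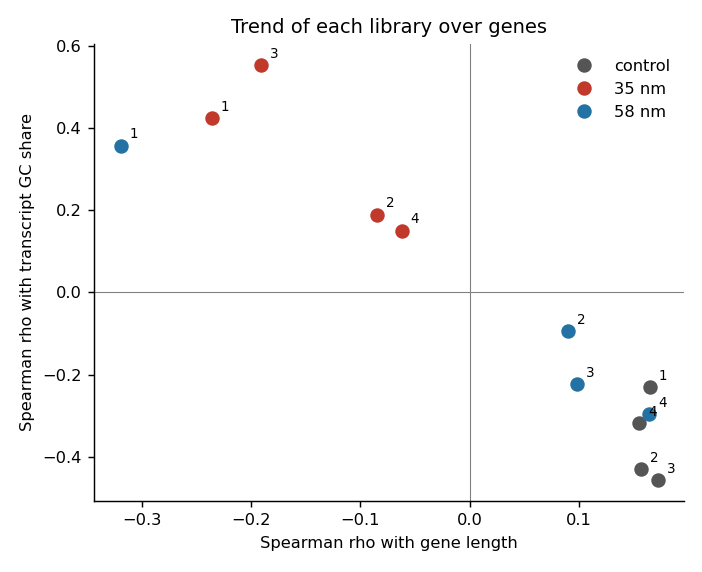
Each point is 1 library, numbered within its group, with Spearman's rho between relative expression and gene length on the x axis and with GC content on the y axis, neither of which has a unit. Controls had the lowest mean rho with GC content (-0.36), 35 nm libraries the highest (0.33), and 58 nm library 1 lay apart from its group at a length rho of -0.319.

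The comparison of 35 nm with control asked how the smaller particle altered the transcriptome. NF-kB target genes, among them the neutrophil chemokines CXCL8 and CXCL1 and the adhesion molecule ICAM1, rose after 35 nm particles in 26 of 29 cases, and the complement component C3, outside that list, rose too. Interferon-stimulated genes such as IFI44L, OAS2 and MX1 fell, with 33 of 37 list members lower. Mitochondrially encoded transcripts fell in 12 of 13 cases. Part of the ribosomal protein genes (45 of 66), nuclear-encoded respiratory subunits (27 of 50), glycolysis and hypoxia genes (21 of 32) and targets of YAP and SRF (19 of 27) rose. With an estimated correlation no list was called, these 7 having adjusted p from 0.0699 to 0.297. Across the transcriptome 4315 of 12176 genes passed, 2463 higher and 1852 lower than control (57.1% higher; upper-quartile rescaling gave 1955 higher and 2419 lower, 44.7% higher), with a median absolute log2 fold change of 0.287. After removal of the length and GC trends, 2504 of the 4315 calls stayed in the same direction, among 3334 calls in all. Groups were fully separated in 36% of genes, where chance gives 2.86%.

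Within the NF-kB list, which collects inflammatory target genes, the median change was 1.03 (camera adjusted p = 8e-15, adjusted p = 0.175 with an estimated correlation; 26 members rose when adjusted over the list alone). CXCL8 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716), which draws neutrophils, rose from 12.6 ± 2.00 to 56.9 ± 13.3 FPKM, a log2 change of 2.07 (SE 0.374, adjusted p = 0.00208). CXCL1, a related chemokine, rose from 22.6 ± 3.08 to 91.6 ± 11.8 FPKM (log2 change 1.98, adjusted p = 0.000302). ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615), which holds leukocytes on endothelium, rose from 19.9 ± 1.44 to 54.9 ± 2.57 FPKM (log2 change 1.42, adjusted p = 9.39e-06). The cytokines IL32, CSF2, IL6 and CCL5 rose by 1.63, 1.65, 1.52 and 1.06 on the log2 scale (adjusted p = 1.94e-07, 0.000353, 0.00266 and 7.45e-06). NFKB1, which codes for the p105 and p50 subunit, rose by 0.58 (adjusted p = 4.48e-06), as did the feedback inhibitors TNFAIP3 by 1.21 and NFKBIA by 1.10. The alternative subunit RELB and the chemokine CXCL6 rose by 1.17 and 1.51. CCL2, a monocyte chemokine, was called at 50.2 ± 1.51 against 32.9 ± 4.65 FPKM (adjusted p = 0.0432). Its adjusted p lay between 0.0523 and 0.107 when any of the 8 libraries compared, or 58 nm library 2 or 4, was left out. Outside the list, C3 (ENSG00000125730, chromosome 19, 6677704 to 6730562), the central complement protein, rose from 2.42 ± 0.12 to 11 ± 0.360 FPKM (log2 change 1.81, SE 0.093, adjusted p = 9.84e-08). CLDN1 (ENSG00000163347, chromosome 3, 190305701 to 190322475), a tight junction claudin of the junction list, rose from 4.07 ± 0.584 to 15.2 ± 1.61 FPKM (log2 change 1.67, adjusted p = 5.49e-06).

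Of 37 interferon-stimulated genes, whose products restrict viruses and present antigen, 33 fell and 1 rose both over all genes and when adjusted over the list alone, with a median change of -0.95 (camera adjusted p = 7.93e-25, adjusted p = 0.157 with an estimated correlation) and of -0.91 after removal of the length and GC trends. IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145) fell from 49.1 ± 7.81 to 9.68 ± 1.38 FPKM (log2 change -2.23, SE 0.124, adjusted p = 2.81e-07). MX1 (ENSG00000157601, chromosome 21, 41420304 to 41459214), a GTPase that blocks viral replication, fell from 137 ± 20.9 to 48.8 ± 1.78 FPKM (log2 change -1.46, adjusted p = 5.13e-07), and its relative MX2 changed by -1.37. OAS2, which senses double-stranded RNA, fell from 134 ± 16.8 to 44.8 ± 2.5 FPKM (log2 change -1.55, adjusted p = 9.84e-08), and XAF1, a pro-apoptotic interferon target, from 25.8 ± 2.20 to 7.84 ± 0.339 FPKM (log2 change -1.60, adjusted p = 3.92e-08). CXCL10, a T-cell chemokine that NF-kB also drives, was the list member that rose, by 1.12 (adjusted p = 0.000186), while IFIT2 stayed at 70.3 against 71.2 FPKM (adjusted p = 0.932).

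**Figure D2:**
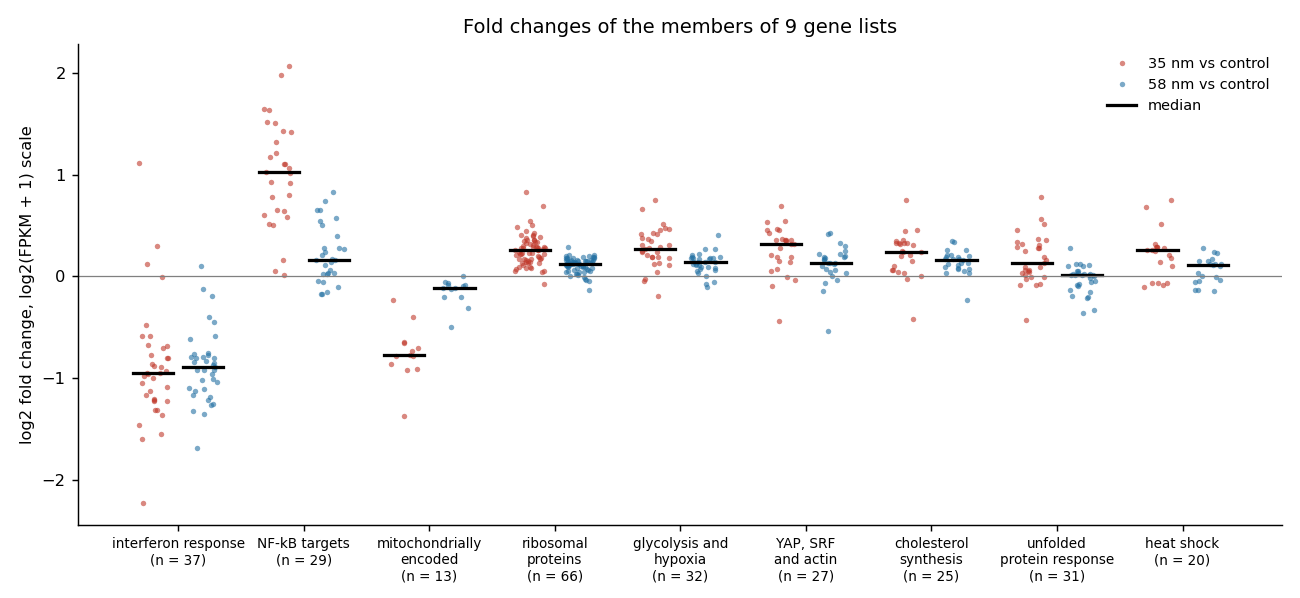
Points are the log2 fold changes against control (y axis) of each tested member of 9 gene lists (x axis), red for 35 nm and blue for 58 nm, with black bars at list medians. Interferon members had a median of -0.95 at 35 nm and -0.89 at 58 nm, whereas NF-kB members had a median of 1.03 at 35 nm and 0.16 at 58 nm.

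Mitochondrially encoded transcripts changed by a median of -0.77 (12 of 13 members fell, and 13 when adjusted over the list alone; camera adjusted p = 4e-15, adjusted p = 0.0699 with an estimated correlation). MT-ND4 (ENSG00000198886, mitochondrial positions 10760 to 12137), a complex I subunit, fell from 2334 ± 149 to 1229 ± 62.2 FPKM (log2 change -0.92, adjusted p = 3.01e-07). Its neighbour MT-ND4L and the ATP synthase subunit MT-ATP6 changed by -0.91 and -0.73 (adjusted p = 2.77e-07 and 3.01e-07). MT-ATP8, of which 22.2% of the exon is shared with a neighbour on the same strand, fell from 121 ± 17.9 to 46.5 ± 9.05 FPKM (log2 change -1.38, adjusted p = 5.29e-05). MT-CO1, a cytochrome oxidase subunit, changed by -0.70 (adjusted p = 4.07e-07); it is the gene with the highest value in each library, so quantile normalization sets its change to 0 by construction. MT-ND3 had a change of -0.23 (adjusted p = 0.0618). It became -0.29 (adjusted p = 0.0301) without 35 nm library 1 and reached adjusted p = 0.0147 and 0.0407 without 58 nm library 1 or 4. The nuclear genes of oxidative phosphorylation went the other way: 27 of 50 rose and 0 fell (29 and 0 when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 7.31e-07, adjusted p = 0.244 with an estimated correlation).

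Ribosomal protein genes, which build the cytosolic ribosome, rose in 45 of 66 cases with 0 falling (49 when adjusted over the list alone; median 0.26, camera adjusted p = 3.63e-13, adjusted p = 0.297 with an estimated correlation). RPL8 rose from 245 ± 12.1 to 398 ± 35.3 FPKM, and RPS3 rose by 0.45 (adjusted p = 0.000111 and 0.000147). Ribosomal proteins have many processed pseudogenes, with which reads may be shared. In the glycolysis and hypoxia list 21 of 32 genes rose and 1 fell (22 and 1 when adjusted over the list alone; median 0.27, camera adjusted p = 5.53e-09, adjusted p = 0.123 with an estimated correlation). The phosphofructokinase PFKP, its activator PFKFB3 and the enolase ENO1 rose by 0.52, 0.48 and 0.42 (adjusted p = 5.49e-06, 2.18e-05 and 2.69e-05), and the lactate exporter SLC16A3 rose by 0.75 (adjusted p = 3.26e-05). Among targets of YAP, SRF and actin dynamics, 19 of 27 rose and 1 fell, also when adjusted over the list alone (median 0.32, camera adjusted p = 6.8e-09, adjusted p = 0.0958 with an estimated correlation). That median was 0.21 after removal of both trends. CYR61 (ENSG00000142871, chromosome 1, 85580761 to 85583962), a secreted matrix protein, rose from 188 ± 6.04 to 304 ± 11.1 FPKM (log2 change 0.69, adjusted p = 3.72e-07). CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373), its relative, rose from 169 ± 6.82 to 244 ± 2.95 FPKM, and the receptor kinase AXL from 109 ± 3.75 to 150 ± 4.01 FPKM (adjusted p = 4.24e-07 and 2.41e-06).

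**Figure D3:**
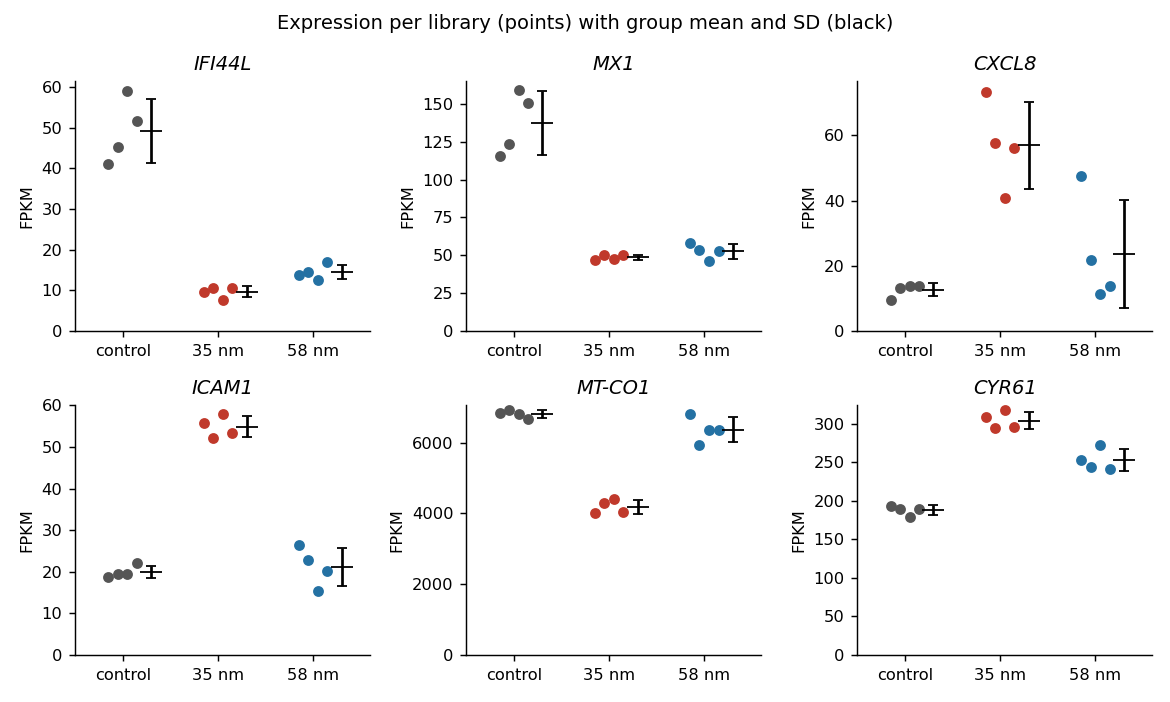
Each point is the FPKM of 1 library for IFI44L, MX1, CXCL8, ICAM1, MT-CO1 and CYR61 in the 3 groups, with the mean and SD of 4 libraries in black and y axes from 0. IFI44L averaged 49.1 in controls against 9.68 and 14.5 FPKM in treated cells, while ICAM1 averaged 54.9 FPKM at 35 nm against 19.9 in controls and 21.2 at 58 nm.

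Heat shock genes, which code for chaperones, rose in 14 of 20 cases (14 when adjusted over the list alone; median 0.26, camera adjusted p = 0.000134, adjusted p = 0.0699 with an estimated correlation). That median was 0.17 after removal of both trends. FKBP4 rose by 0.68 and HSPE1 by 0.75. Cholesterol synthesis genes rose in 18 of 25 cases with 1 falling, both over all genes and when adjusted over the list alone (median 0.24, camera adjusted p = 2.2e-06, adjusted p = 0.123 with an estimated correlation). Unfolded protein response genes rose in 14 of 31 cases, with 1 lower when adjusted over the list alone (median 0.14, camera adjusted p = 0.000659, adjusted p = 0.238 with an estimated correlation). Its chaperone HSPA5 rose from 120 ± 2.95 to 150 ± 4.97 FPKM (adjusted p = 3.7e-05), and HYOU1 and SDF2L1 rose by 0.51 and 0.78. Genes of iron handling and ferroptosis rose in 9 of 21 cases (9 when adjusted over the list alone; median 0.16, camera adjusted p = 0.00996, adjusted p = 0.175 with an estimated correlation). The transferrin receptor TFRC rose by 0.69 (adjusted p = 1.94e-07) and the ferritin heavy chain FTH1 by 0.60 (adjusted p = 0.00116). Basement membrane genes rose in 15 of 30 cases and fell in 4 (15 and 5 when adjusted over the list alone; median 0.15, camera adjusted p = 0.00397, adjusted p = 0.244 with an estimated correlation, and 0.188 under quantile normalization). The collagen COL4A1 rose by 0.31. Immediate early genes rose in 9 of 23 cases and fell in 1 (9 and 2 when adjusted over the list alone; median 0.15, camera adjusted p = 0.0108, adjusted p = 0.262 with an estimated correlation, and 0.198 after removal of the length and GC trends). They were also not called after removal of the length trend, with a filter at 5 FPKM or under quantile normalization (0.0611, 0.0663 and 0.0569). JUNB rose by 0.83. NRF2 targets of the oxidative stress response rose in 8 of 22 cases and fell in 1, also when adjusted over the list alone (median 0.12, camera adjusted p = 0.0368, adjusted p = 0.238 with an estimated correlation). That adjusted p was 0.0537 without control library 1, 0.0589 under upper-quartile rescaling, 0.18 under quantile normalization, 0.15 with a filter at 5 FPKM, 0.121 after removal of the length trend and 0.178 after removal of both trends. Quantile normalization brought list medians nearer 0 for targets of YAP and SRF (0.20), oxidative phosphorylation (0.17), cholesterol synthesis (0.12), heat shock (0.11), ribosomal proteins (0.094) and the unfolded protein response (0.063), all of them still called with camera. The iron and ferroptosis median was 0.10 without the filter, 0.099 after removal of the length trend and 0.24 with limma-voom. HMOX1, the NRF2 target heme oxygenase 1, rose from 8.96 ± 0.771 to 11.4 ± 0.980 FPKM (adjusted p = 0.00682, and 0.0843 after removal of both trends).

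The junction list, with 2 of 19 higher and 2 lower, and the endothelial identity list, with 1 of 17 higher and 2 lower, had medians of -0.062 and -0.017 (camera adjusted p = 0.549 and 0.974). The efflux pump ABCB1 fell from 3.00 ± 0.241 to 2.16 ± 0.190 FPKM (adjusted p = 0.00261). TJP1, a scaffold of tight junctions, fell from 26.6 ± 0.954 to 22.5 ± 1.24 FPKM (adjusted p = 0.0157, and 0.0511 without 35 nm library 1). The glucose transporter SLC2A1 rose from 40.1 ± 2.38 to 47.5 ± 3.40 FPKM (adjusted p = 0.0165). It had 0.0522 and 0.0509 without 35 nm library 1 or 3 and 0.0888 after removal of both trends. OCLN, CDH5 and PECAM1, which code for occludin, VE-cadherin and CD31, had adjusted p = 0.12, 0.202 and 0.283. CDH5 and PECAM1 averaged 1.44 and 1.42 FPKM in controls, near the filter, where fold changes are understated. CDH5 passed without 35 nm library 2 (0.0355) and OCLN without control library 3 (0.042). CLDN5, the main claudin of this barrier, averaged 0.117 FPKM in controls, 0.093 at 35 nm and 0.095 at 58 nm, below the filter. The transporter and receptor list had 12 of 24 genes higher and 4 lower (13 and 6 when adjusted over the list alone) at an adjusted p of 0.0548. That was 0.046, 0.0444, 0.038 and 0.0484 without control 2, control 4, 35 nm 3 or 58 nm 3. It was 0.00289 without the filter, 0.0472 under upper-quartile rescaling, 0.0219 after removal of the length trend and 0.0368 with limma-voom. CDKN1A, the p21 inhibitor of the cell cycle, rose from 86.9 ± 1.65 to 115 ± 7.66 FPKM (adjusted p = 0.000372). The sterol enzyme HMGCS1 had a change of 0.11 (adjusted p = 0.0345), and of -0.031 under quantile normalization. It lost its call (0.0529 to 0.0936) without control 1, 3 or 4 or without 35 nm 1, 2 or 4. The stress factor DDIT3 had a change of -0.43 (adjusted p = 0.0503). It passed (0.0284 to 0.0482) without control 1, control 2, 35 nm 3, 58 nm 1 or 58 nm 3. NQO1, SLC7A11, ATF3, GDF15, SQSTM1, MT2A and MKI67 had adjusted p = 0.149, 0.828, 0.482, 0.565, 0.702, 0.662 and 0.177. NQO1 reached 0.0344 without 58 nm library 1, and SLC7A11 0.0185 after removal of both trends.

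Among the other lists, p53 targets (8 of 27 higher, 1 lower) and apoptosis genes (12 of 28 higher, 2 lower) both had an adjusted p of 0.0671. It was 0.0335 and 0.045 for p53 targets without control 4 or 35 nm 3 and 0.044 without 58 nm 1, and 0.0335 and 0.038 for apoptosis genes without control 4 or 35 nm 3. After removal of the length and GC trends, apoptosis genes passed (0.0289). Replication histones, S phase, coagulation and G2/M genes had adjusted p = 0.0843, 0.0844, 0.135 and 0.142, and histones passed after removal of both trends (0.0154) or of the length trend (0.0438). G2/M genes had a median of -0.065, but of -0.15 under quantile normalization (adjusted p = 0.00162) and of -0.098 after removal of the length trend (adjusted p = 0.0205). Without the filter S phase, coagulation, p53 and apoptosis genes passed (0.00141, 0.0394, 0.00805 and 0.00458), and p53 targets also in a fit of the 8 libraries compared, with limma-voom and with array weights (0.043, 0.0481 and 0.0486). Lysosome, autophagy and endocytosis genes, which handle particles taken up, had medians of -0.014, -0.010 and 0.017 (adjusted p = 0.348, 0.348 and 0.359). With both trends removed the lysosome list had a median of -0.075 (adjusted p = 0.00641), and under quantile normalization of -0.086 (adjusted p = 0.0455). Matrix proteases, angiogenesis and inflammasome genes each had an adjusted p of 0.862, and TGF-beta signalling had 0.963. The 5 metallothioneins had a median of 0.027 but a mean of -0.022 (adjusted p = 0.498). Markers of epithelium, fibroblasts and pericytes had adjusted p = 0.808, 0.549 and 0.917. Of the astrocyte and leukocyte markers 3 and 0 genes passed the filter, too few for a test.

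The comparison of 58 nm with control asked the same of the larger particle. Interferon-stimulated genes fell to nearly the levels seen at 35 nm, with 34 of 37 list members lower, and IFI44L, MX1, MX2 and OAS2 had the largest falls among called genes of at least 5 FPKM. The sterol enzyme MVD, the YAP and SRF targets CTGF and CYR61, and the polyamine enzyme ODC1 rose by 0.33 to 0.46 on the log2 scale. In total 503 genes passed, 265 higher and 238 lower (52.7% higher; upper-quartile rescaling gave 197 higher and 260 lower, and quantile normalization 189 and 259, 42.2% higher). The median absolute log2 fold change of called genes was 0.281, and 13.5% of genes had fully separated groups, where chance gives 2.86%. Leaving out control 2, 3 or 4 or 58 nm library 2 or 3 lowered the count to 262, 228, 287, 270 and 319.

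The interferon list had a median change of -0.89 (34 fell and 0 rose, 35 and 0 when adjusted over the list alone; camera adjusted p = 4.12e-63, adjusted p = 0.0776 with an estimated correlation), and -0.88 after removal of the length and GC trends. IFI44L fell from 49.1 ± 7.81 to 14.5 ± 1.8 FPKM (log2 change -1.69, SE 0.124, adjusted p = 6.4e-06). MX1 fell to 52.8 ± 4.91 FPKM (log2 change -1.35, SE 0.095, adjusted p = 3.54e-06) and MX2 to 7.90 ± 0.859 FPKM (-1.32, adjusted p = 3.54e-06). OAS2 and XAF1 fell to 54.7 ± 3.57 and 10.2 ± 0.850 FPKM (adjusted p = 1.19e-06 and 8.23e-07). CMPK2, a mitochondrial nucleotide kinase that interferon induces, fell from 35.0 ± 6.98 to 14.3 ± 1.86 FPKM (adjusted p = 0.000207). The ubiquitin-like ISG15 fell from 739 to 391 FPKM (log2 change -0.92, adjusted p = 0.000187).

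Cholesterol synthesis genes rose in 7 of 25 cases over all genes, and 16 rose and 1 fell when adjusted over the list alone (median 0.16, camera adjusted p = 4.32e-09, adjusted p = 0.0857 with an estimated correlation). MVD, an enzyme of the mevalonate pathway, rose from 32.9 ± 1.60 to 41.8 ± 3.19 FPKM (log2 change 0.33, SE 0.063, adjusted p = 0.010). Squalene synthase FDFT1 rose by 0.21 (adjusted p = 0.00688, and 0.0531 under quantile normalization). Targets of YAP, SRF and actin rose in 11 of 27 cases and fell in 1 (17 and 2 when adjusted over the list alone; median 0.14, camera adjusted p = 8.08e-08, adjusted p = 0.0971 with an estimated correlation). CTGF rose from 169 ± 6.82 to 225 ± 6.14 FPKM, CYR61 from 188 ± 6.04 to 253 ± 14.2 FPKM and AJUBA from 23.1 ± 1.2 to 27.6 ± 0.620 FPKM (adjusted p = 1.25e-05, 8.02e-05 and 0.00774). Outside these lists, ODC1 (ENSG00000115758, chromosome 2, 10439968 to 10448504) rose from 34.1 ± 1.01 to 47.3 ± 3.91 FPKM (log2 change 0.46, SE 0.052, adjusted p = 0.000156), and GCAT, an enzyme of threonine breakdown, by 0.52 (adjusted p = 0.012, and 0.0515 without the filter). The decoy receptor TNFRSF10D had a change of 0.46 (adjusted p = 0.0178), with 0.0551 to 0.0608 without control 2, control 4, 58 nm 2 or 58 nm 3. The pseudogenes SMURF2P1 and TMSB4XP8 and the nucleotide hydrolase DNPH1 had changes of 0.55, 0.45 and 0.48 (adjusted p = 0.0272, 0.026 and 0.0355). Pseudogenes share reads with their parent genes. SMURF2P1 lost its call (0.0573 to 0.0804) without control 2, 3 or 4 or 58 nm 1 or 2. TMSB4XP8 lost its call (0.0518 to 0.0733) without control 3 or 4 or 58 nm 1, 2 or 4, and DNPH1 lost its call (0.0508 to 0.0849) without control 1, 2 or 4, 35 nm 2, or 58 nm 1 or 2. After removal of the length and GC trends DNPH1 had 0.0548.

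Ribosomal protein genes had a median of 0.12 (camera adjusted p = 4.32e-09, adjusted p = 0.404 with an estimated correlation; 2 of 66 rose over all genes, 0 when adjusted over the list alone). That median was 0.068 without 58 nm library 1. RPL10 and RPL6 had changes of 0.20 and 0.15 (adjusted p = 0.0331 and 0.0462). RPL10 did not pass (0.0595 to 0.0959) without any 1 control or 58 nm library 2. RPL6 did not pass (0.0546 to 0.129) without any 1 of the 12 libraries other than 35 nm 3 and 58 nm 4. Glycolysis and hypoxia genes rose in 6 of 32 cases (13 when adjusted over the list alone; median 0.14, camera adjusted p = 2.48e-07, adjusted p = 0.167 with an estimated correlation). PGAM1, LDHA and GAPDH, all enzymes of lower glycolysis, had changes of 0.18, 0.21 and 0.19 (adjusted p = 0.0171, 0.0222 and 0.0335). PGAM1 lost its call (0.0525 to 0.0686) without control 2, 3 or 4 and after removal of both trends, LDHA (0.0566 to 0.0653) without control 1, control 4 or 58 nm 2, and GAPDH (0.066 to 0.103) without any 1 control or 58 nm 2. Mitochondrially encoded transcripts had a median of -0.11, which was -0.067 without 58 nm library 2 (camera adjusted p = 2.63e-05, adjusted p = 0.17 with an estimated correlation). Of 13 members 1 fell, and 4 when adjusted over the list alone. MT-ND4L fell from 2185 ± 152 to 1759 ± 110 FPKM (adjusted p = 0.00766, and 0.506 under quantile normalization). MT-ND2 and MT-ND4 had changes of -0.20 and -0.21 (adjusted p = 0.0576 and 0.0652). These were 0.0228 and 0.0388 without 58 nm library 1, 0.0363 for MT-ND2 without 35 nm library 3 and 0.0428 for MT-ND4 without control 4.

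Of the remaining lists that were called, oxidative phosphorylation had a median of 0.095 with 0 of 50 members called over all genes or when adjusted over the list alone (camera adjusted p = 0.000182, adjusted p = 0.353 with an estimated correlation), and 0.058 without 58 nm library 1. S phase genes had a median of 0.092 with 3 of 33 higher (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000257, adjusted p = 0.0971 with an estimated correlation). Immediate early genes had a median of 0.13 with 1 of 23 lower (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.00723, adjusted p = 0.301 with an estimated correlation, and 0.10 after removal of both trends), and 0.077 without 58 nm library 1. The NF-kB list had a median of 0.16 with 1 of 29 higher (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.00807, adjusted p = 0.559 with an estimated correlation). Without 58 nm library 1 that median was 0.083 (adjusted p = 0.26), and the list was not called with array weights (0.0916) or a filter at 5 FPKM (0.105). Its members CXCL8, IL6 and ICAM1 stood at 23.6 ± 16.6, 3.89 ± 2.68 and 21.2 ± 4.61 FPKM (adjusted p = 0.371, 0.19 and 0.824). Heat shock, with 1 of 20 higher (10 higher and 1 lower when adjusted over the list alone), had a median of 0.11 (camera adjusted p = 0.0268, adjusted p = 0.17 with an estimated correlation, 0.0886 after removal of the length trend, and 0.226 with a median of 0.047 under quantile normalization). G2/M genes had a median of 0.058 (2 of 34 higher, 4 when adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.301 with an estimated correlation). They lost the call without control 2 (0.0666) or 58 nm library 3 (0.0932, median 0.033). They also lost it under quantile normalization (0.263, median 0.018), after removal of the length trend (0.0791) and with a filter at 5 FPKM (0.0892). Basement membrane genes had a median of 0.083 (3 of 30 higher, 7 when adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.353 with an estimated correlation, 0.0672 after removal of both trends, 0.235 under quantile normalization, 0.0977 with a filter at 5 FPKM and 0.144 without 58 nm library 2). Metallothioneins, which bind metal ions, had a median of -0.21 with 0 of 5 lower (3 when adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.149 with an estimated correlation, 0.0821 without the filter and 0.0795 without 58 nm library 4). Endocytosis genes had a median of 0.062 (2 of 32 higher, also when adjusted over the list alone; camera adjusted p = 0.0417, adjusted p = 0.17 with an estimated correlation). The call was lost without control 3 (0.0743), 35 nm library 2 (0.0521) or 58 nm library 2 or 3 (0.0803 and 0.0868), and after removal of both trends (0.116) or of the length trend (0.0724). It was also lost under upper-quartile rescaling (0.072), quantile normalization (0.423), a filter at 5 FPKM (0.144) and limma without trend and robust prior (0.0529).

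At the barrier, ABCB1 fell from 3.00 ± 0.241 to 2.01 ± 0.121 FPKM (log2 change -0.41, SE 0.071, adjusted p = 0.00527). OCLN, TJP1, CDH5, PECAM1 and SLC2A1 had adjusted p = 0.497, 0.689, 0.693, 0.723 and 0.0921, and the transporter, junction and endothelial lists 0.56, 0.594 and 0.594. ATF3, HMGCS1 and SQSTM1 were called with changes of -0.33, 0.17 and -0.17 (adjusted p = 0.0355, 0.0195 and 0.0417). Each lost its call without single libraries, which were control 3 or 4 or 58 nm 2, 3 or 4 for ATF3 (0.0566 to 0.107), control 3 or 4 or 58 nm 2 or 3 for HMGCS1 (0.0556 to 0.0735), and control 2, 3 or 4, 35 nm 2 or 4, or 58 nm 2, 3 or 4 for SQSTM1 (0.0512 to 0.118). HMOX1, NQO1, SLC7A11, CCL2, DDIT3, HSPA5, CDKN1A, MT2A and MKI67 had adjusted p = 0.546, 0.448, 0.579, 0.837, 0.231, 0.427, 0.544, 0.181 and 0.645. GDF15 had 0.18, and a change of -0.36 (adjusted p = 0.000754) without 58 nm library 1, with 0.0105 after removal of both trends. The lists not called had adjusted p from 0.115 for iron and ferroptosis to 0.992 for coagulation. They included unfolded protein response (0.594), lysosome (0.182), autophagy (0.268), p53 (0.942), apoptosis (0.726), NRF2 (0.387) and TGF-beta (0.307). The others were matrix proteases, angiogenesis, inflammasomes, replication histones and the markers of epithelium, fibroblasts and pericytes (0.182, 0.247, 0.251, 0.594, 0.794, 0.268 and 0.679). Without 58 nm library 1 the lysosome, protease and inflammasome lists passed (0.0353, 0.0385 and 0.0275), and the lysosome list also after removal of both trends (0.0107). The lysosome and protease lists each had 0.0234 under quantile normalization, and proteases 0.0381 with a filter at 5 FPKM. Quantile normalization brought the medians of S phase (0.057), ribosomal protein (0.064) and mitochondrially encoded genes (-0.020) nearer 0, each still called with camera, and the NF-kB median was 0.11 without the filter.

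The comparison of 58 nm with 35 nm tested the difference between both sizes directly. NF-kB targets such as IL32 and ICAM1 were lower at 58 nm, 24 of 29 members being so, and C3, outside that list, was lower too. Mitochondrially encoded transcripts were higher, in 12 of 13 cases, and HYOU1 and CALR, chaperones of the endoplasmic reticulum, were lower. The interferon list was not called, with a median of 0.033 (camera adjusted p = 0.356; 5 of 37 higher and 3 lower, 8 and 3 when adjusted over the list alone). Without 58 nm library 3 it had 0.078 (adjusted p = 0.0248), and under quantile normalization 0.092 (adjusted p = 0.0338). In all, 1382 genes passed, 431 higher and 951 lower at 58 nm (31.2% higher; upper-quartile rescaling gave 655 and 703, 48.2% higher, and quantile normalization 540 and 693, 43.8% higher), with a median absolute log2 fold change of 0.27. Groups were fully separated in 16.2% of genes, where chance gives 2.86%. The count was 2324 without 58 nm library 1, and 801, 883, 768 and 723 without 35 nm library 1, 35 nm library 3, 58 nm library 3 or 58 nm library 4.

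The NF-kB list had a median of -0.78 (28 members lower when adjusted over the list alone; camera adjusted p = 4.09e-22, adjusted p = 0.070 with an estimated correlation). IL32 stood at 6.13 ± 1.23 against 17.6 ± 1.31 FPKM (adjusted p = 7.46e-06) and ICAM1 at 21.2 ± 4.61 against 54.9 ± 2.57 FPKM (log2 change -1.35, SE 0.122, adjusted p = 7.53e-05). The cytokine IL1B and the superoxide dismutase SOD2 fell by 1.10 and 0.87 (adjusted p = 0.00555 and 0.000273). CXCL1 was lower by 1.14 (adjusted p = 0.0193). Its adjusted p was 0.0583 without 35 nm library 1 and 0.0544 and 0.0632 without 58 nm library 3 or 4. CXCL8 had a change of -1.42 (adjusted p = 0.0377), with 0.0528 to 0.109 without control 2, 3 or 4, 35 nm 1, 2 or 4, or 58 nm 2, 3 or 4. IL6 and CCL2 had adjusted p = 0.114 and 0.0536, and 0.00122 and 0.000297 without 58 nm library 1. Outside the list, C3 stood at 3.58 ± 0.80 against 11 ± 0.360 FPKM (log2 change -1.40, SE 0.093, adjusted p = 7.13e-06), and CLDN1 fell by 1.30 (adjusted p = 0.000247).

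Mitochondrially encoded transcripts had a median of 0.60 (12 higher, also when adjusted over the list alone; camera adjusted p = 4.76e-22, adjusted p = 0.0232 with an estimated correlation). MT-ND6 stood at 902 ± 55.4 against 524 ± 36.8 FPKM (log2 change 0.78, SE 0.057), MT-ATP6 at 2563 ± 152 against 1671 ± 57.5 FPKM and MT-ND5 at 900.0 ± 32.8 against 602 ± 28.3 FPKM (adjusted p = 9.86e-06 for each; MT-ND5 0.0628 under quantile normalization). MT-ATP8 and, outside the list, the transfer RNA MT-TR and the nuclear pseudogene MTATP6P1, which shares sequence with MT-ATP6, rose by 0.88, 1.06 and 0.79 (adjusted p = 0.00374, 0.00493 and 0.00434). The transfer RNA MT-TL1, also outside it, had a change of 0.81 (adjusted p = 0.021), and 0.0515 to 0.0664 without 35 nm 2, 35 nm 3, 58 nm 3 or 58 nm 4 and after removal of both trends. The small RNA genes MIR590 and SNORD62B were called on averages of 12 against 3 and 9 against 4 reads (adjusted p = 0.0219 and 0.0212). MIR590 lost its call (0.0549 to 0.0635) without 35 nm 1, 58 nm 3 or 58 nm 4, and SNORD62B (0.0519 to 0.0674) without 35 nm 2, 58 nm 2 or 58 nm 4.

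Heat shock genes were lower at 58 nm in 8 of 20 cases (12 when adjusted over the list alone; median -0.14, camera adjusted p = 6.63e-06, adjusted p = 0.0279 with an estimated correlation). Unfolded protein response genes were lower in 13 of 31 cases (19 when adjusted over the list alone; median -0.18, camera adjusted p = 1.44e-08, adjusted p = 0.0695 with an estimated correlation). HYOU1 and CALR, chaperones of that response, and the secreted STC2 stood at 18.1 ± 0.512, 277 ± 7.49 and 31.4 ± 1.86 FPKM against 24.1 ± 0.766, 355 ± 20.4 and 44.5 ± 2.73 FPKM (adjusted p = 6.96e-05, 0.000582 and 0.000638), and HSPA5 at 125 ± 3.78 against 150 ± 4.97 FPKM (adjusted p = 0.000852). Targets of YAP, SRF and actin were lower in 10 of 27 cases (14 when adjusted over the list alone; median -0.12, camera adjusted p = 3.49e-08, adjusted p = 0.0695 with an estimated correlation). AXL, the actin crosslinkers ACTN1 and FLNA, and the glycolysis genes PFKP, PFKFB3 and PGK1 fell by 0.27, 0.27, 0.26, 0.34, 0.37 and 0.22 (adjusted p = 0.000852, 0.000869, 0.00133, 0.000852, 0.000891 and 0.00301). Glycolysis and hypoxia genes were lower in 13 of 32 cases (16 when adjusted over the list alone; median -0.18, camera adjusted p = 1.62e-06, adjusted p = 0.111 with an estimated correlation). Ribosomal protein genes were lower in 15 of 66 cases and higher in 1 (26 and 1 when adjusted over the list alone; median -0.14, camera adjusted p = 2.01e-08, adjusted p = 0.492 with an estimated correlation, and 0.0574 under quantile normalization). RPS3 and RPL8 had changes of -0.33 and -0.49 (adjusted p = 0.00468 and 0.00496). Oxidative phosphorylation genes were lower in 10 of 50 cases (15 when adjusted over the list alone; median -0.13, camera adjusted p = 3.78e-05, adjusted p = 0.362 with an estimated correlation). G2/M genes were higher in 10 of 34 cases (14 higher and 1 lower when adjusted over the list alone; median 0.11, camera adjusted p = 6.63e-06, adjusted p = 0.0695 with an estimated correlation).

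Apoptosis genes were lower in 7 of 28 cases and higher in 1 (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.070 with an estimated correlation). Barrier transporters and receptors were lower in 8 of 24 cases (9 lower and 1 higher when adjusted over the list alone; median -0.10, and -0.058 without 35 nm library 1; camera adjusted p = 0.00747, adjusted p = 0.0695 with an estimated correlation). Iron and ferroptosis genes were lower in 7 of 21 cases (8 when adjusted over the list alone; median -0.14, with -0.062 and -0.088 without 35 nm library 2 or 58 nm library 1, -0.079 after removal of both trends and -0.067 without the filter; camera adjusted p = 0.00747, adjusted p = 0.111 with an estimated correlation). p53 targets were lower in 9 of 27 cases (10 when adjusted over the list alone; median -0.10, -0.066 without 35 nm library 1 and -0.057 after removal of both trends; camera adjusted p = 0.0101, adjusted p = 0.188 with an estimated correlation). CDKN1A was lower by 0.32 (adjusted p = 0.00553). Coagulation genes were lower in 5 of 17 cases and higher in 1 (9 and 3 when adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.070 with an estimated correlation, and 0.0798 under quantile normalization). Basement membrane genes were lower in 8 of 30 cases and higher in 2 (10 and 3 when adjusted over the list alone; camera adjusted p = 0.00868, adjusted p = 0.331 with an estimated correlation, 0.266 under quantile normalization, 0.0618 with array weights and 0.166 without 58 nm library 1). Their median was -0.075, and -0.033 after removal of both trends. NRF2 targets, replication histones and cholesterol synthesis genes had medians of -0.10, 0.13 and -0.071 (camera adjusted p = 0.0343, 0.0415 and 0.0448; adjusted p = 0.221, 0.111 and 0.433 with an estimated correlation). Members lower numbered 3 of 22, 0 of 13 and 4 of 25, and 4, 0 and 4 when adjusted over the list alone. NRF2 targets lost the call (0.0505 to 0.0676) without 35 nm 3 or 58 nm 2 or 3, and histones (0.0584 to 0.0946) without 35 nm 2 or 3 or 58 nm 1 or 2. Cholesterol synthesis lost it (0.0537 to 0.134) without control 2, 35 nm 1 or 3, or 58 nm 1 or 4, with a median of -0.027 without 35 nm 3. After removal of both trends NRF2 targets and cholesterol synthesis were not called (0.187 and 0.0907). NRF2 targets were not called either under upper-quartile rescaling, quantile normalization, a filter at 5 FPKM or removal of the length trend (0.0605 to 0.165). Histones were not called under both rescalings, both other filters or limma-voom (0.0512 to 0.12). Cholesterol synthesis was not called under both rescalings, a filter at 5 FPKM, removal of the length trend, array weights or limma without trend and robust prior (0.0582 to 0.818, the median being -0.0071 under quantile normalization). Quantile normalization brought the medians of heat shock (-0.065), glycolysis (-0.079) and oxidative phosphorylation (-0.084) nearer 0, each still called with camera.

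Of the panel, SQSTM1 was lower by 0.19 at 58 nm (adjusted p = 0.0122). GDF15 had a change of -0.32 (adjusted p = 0.0493), and lost its call (0.0515 to 0.137) without any of the 12 libraries other than 58 nm 1. TJP1, MKI67, MT2A and HMOX1 had adjusted p = 0.102, 0.09, 0.0606 and 0.0798, and 0.0058, 0.00877, 0.00754 and 0.0263 without 58 nm library 1. MT2A also passed without 35 nm library 2 (0.0407), and ATF3 (0.0579) without control 1, control 4 or 58 nm 1 (0.0271 to 0.0495). OCLN, CDH5, PECAM1, SLC2A1, ABCB1, NQO1, SLC7A11, DDIT3 and HMGCS1 had adjusted p = 0.655, 0.603, 0.17, 0.903, 0.559, 0.791, 0.371, 0.798 and 0.269. After removal of both trends SLC7A11, MKI67 and CCL2 passed (0.0239, 0.0328 and 0.047). Immediate early genes had 0.0836, and 0.0499 and 0.0232 without 35 nm library 4 or 58 nm library 1 and 0.0188 without the filter. The other lists had adjusted p from 0.454 for inflammasomes to 0.896 for fibroblast markers. Among them were junctions (0.841), endothelial identity (0.769), lysosome (0.531), autophagy (0.593), endocytosis (0.799) and metallothioneins (0.492). The lysosome list passed after removal of both trends (0.0387).

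Fold changes against the same controls were compared between both sizes. Interferon genes such as IFI44L fell in both comparisons, ABCB1 fell in both, and CYR61 and CTGF rose in both. Of the called genes, 241 were higher in both, 214 lower in both and 0 opposite, where independent lists would share 53.6, 36.2 and 88.5. Across genes the fold changes correlated at r = 0.675, against 0.503 (0.438 to 0.551) in 60 simulations of unchanged groups with these controls. The covariance was 0.0356 against 0.00894, a difference of 0.0267. The simulations drew each gene and library independently and held no length or GC trend, so their range may be too narrow. Without 58 nm library 1 the observed r was 0.584, nearer to that range. With the controls split so that each comparison had its own pair, r was 0.387 to 0.46 and the covariance 0.0249 to 0.0282. Signs matched in 78.2% of genes, in 66.7% of simulated ones and in 69.3% to 72.1% with split controls. Groups simulated as unchanged shared 0 calls, a value for no effect that is no reference where both comparisons hold effects. With split controls 29 to 80 genes were higher and 102 to 133 lower in both, where independent lists would share 5.18 to 15 and 10.3 to 14.9. Opposite calls then numbered 0 to 3. Of 3860 genes called at 35 nm alone, 1127 differed between the sizes when tested directly, and of 48 called at 58 nm alone, 22 did.

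**Figure D4:**
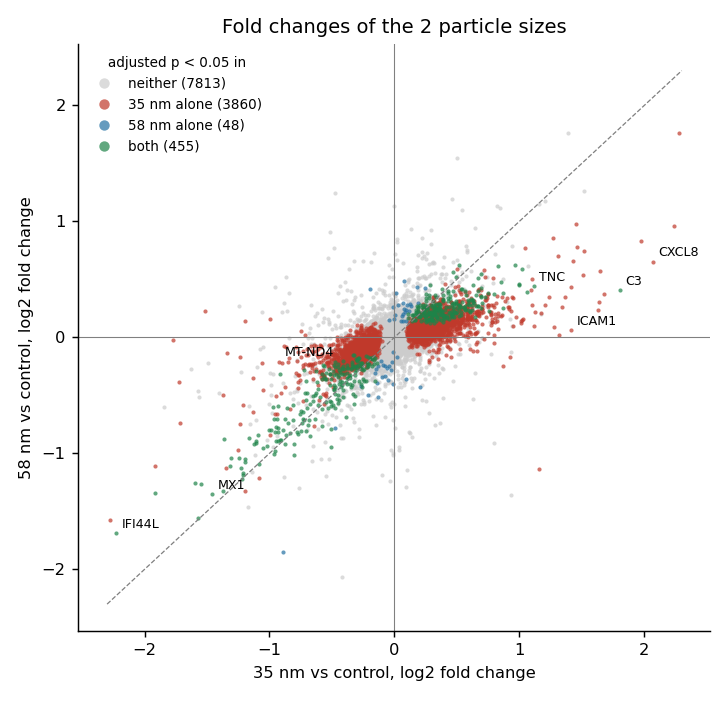
Each point is 1 gene, with its log2 fold change of 35 nm against control on the x axis and of 58 nm against control on the y axis, coloured by the comparisons in which it was called; the dashed line marks equal changes. The 455 genes called in both lie on the same side of 0, and 3860 were called at 35 nm alone.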

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

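The tests of gene length and GC content on the interferon and NF-kB genes, of the state of the control cultures, of particle number and of a mislabelled 35 nm sample were chosen only after the result was seen. Changes below are list medians on the log2 scale.

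Interferon-stimulated genes were lower after both particle sizes, and in 33 of 37 the 4 controls lay above all 8 treated libraries, where chance gives 0.202% for a single gene. The members move together (estimated correlation 0.596), so they do not count as 37 independent results. The tables argue against the libraries' gene length and GC trends as the whole cause: with both removed, the median was still -0.91 at 35 nm and -0.88 at 58 nm. Nor did the fall rest on a single control, since over both sizes and each control left out in turn the median stayed between -1.01 and -0.85. Whether the particles lowered these genes or the control cultures carried a raised interferon state cannot be told apart, because the difference between both treated groups was 0.033 and the design has 1 set of controls. No batch is given in the labels, so a batch shared by the treated libraries is untested.

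NF-kB targets differed between both sizes at the preset correlation, with a median of -0.778 for 58 nm against 35 nm, and were not called with an estimated correlation (adjusted p = 0.070). After removal of the length and GC trends the median was -0.78, which argues against those trends as its cause. Leaving out each of the 8 treated libraries in turn gave -0.97 to -0.67, so the difference did not rest on a single library. Particle size may act here through particle number: at equal mass and density the 35 nm particles would be 4.55 times as many, and with 1 mass dose per size these cannot be told apart.

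Library 1 of the 58 nm group lay apart from its group, holding 13 of the 35 values that stood far from the other 3 libraries of their group. Chance flags about 1 in 20 groups, or 24.8 of the 495 tested. A 35 nm sample under a wrong label, or mixed in, is argued against by its share of mitochondrial reads, 3.11% (3.104% to 3.125%, 95% exact interval), where the other 58 nm libraries had at most 2.9% and the 35 nm libraries at most 1.95%. Its gene length and GC trend may account for part of the distance: the ratio of its distance from the group to the distance among the others went from 2.16 to 1.51 with the trend removed, too close to the bound of 1.5 given the lowest single ratio of 1.4. Removal of the trend changed its NF-kB score little, which lay 0.43 above the next 58 nm library before removal and 0.4 after it (SE 0.06 over members). That SE takes the members as independent, although their estimated correlation was 0.526, so it is too small, and it compares 1 library with 1 other. A biological difference of that culture stays open and untested.

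In that library the rho between expression and gene length was -0.319, and the scores of NRF2, autophagy and inflammasome genes were 0.093, 0.021 and 0.068. Its FPKM values apart from the other 58 nm libraries were 4.76 for C3, 76 for CXCL1, 7.96 for IL32, 41.8 for NFKBIA, 12 for SOD2, 28.5 for GDF15, 358 for ENO1, 582 for GAPDH and 135 for TIMP2. Each other library held 0 to 5 flagged values. Since chance gives about 24.8 over all libraries, the values that follow may have arisen by chance. Library 1 of the 35 nm group stood apart in the scores of NF-kB (1.14), p53 (0.189) and apoptosis genes (0.184) and in COL4A1 (31.1 FPKM) and MT-ND3 (535 FPKM). Library 3 of that group did so in the share of reads of the 10 highest genes (4.88%), the lysosome score (0.017), DDIT3 (6.96 FPKM), GAPDH (594 FPKM) and LDHA (137 FPKM), and library 4 in SDF2L1 (24.7 FPKM). Library 3 of the 58 nm group stood apart in the scores of G2/M genes (0.089) and matrix proteases (-0.117), and library 2 in fibroblast markers (0.08) and CTGF (234 FPKM). Among controls, library 1 stood apart in the iron and ferroptosis score (-0.047), CLDN1 (3.2 FPKM) and HSPE1 (7.67 FPKM), library 2 in PECAM1 (1.67 FPKM) and library 3 in FKBP4 (11.3 FPKM). Control library 4 did so in the p53 score (0.054) and CALR (276 FPKM).

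Other lists were called between both sizes by the direct test of 58 nm against 35 nm at the preset correlation. Mitochondrially encoded genes, with a median of 0.603, and heat shock genes, with -0.142, were also called with an estimated correlation (adjusted p = 0.0232 and 0.0279). The lists that follow were not, with adjusted p from 0.0695 to 0.492 at that setting. Replication histones had a median of 0.132 and G2/M genes of 0.112. The negative ones were the unfolded protein response (-0.184), glycolysis and hypoxia (-0.176), ribosomal proteins (-0.142), iron and ferroptosis (-0.136), oxidative phosphorylation (-0.13) and apoptosis (-0.122). The remaining ones were targets of YAP and SRF (-0.121), coagulation (-0.111), NRF2 (-0.104), p53 (-0.103), barrier transporters (-0.1), basement membrane (-0.075) and cholesterol synthesis (-0.071).

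The 8 libraries of each comparison can be split in 35 ways. For counts of genes, 1 of 35 splits, the real one, reached the real count in each comparison, the smallest share possible. Counts were 4315 genes against at most 1 in another split for 35 nm against control, 503 against 1 for 58 nm against control, and 1382 against 4 for 58 nm against 35 nm. Every other split mixes both groups, so a real difference widens its spread and lowers its count. The low counts of other splits are therefore no measure of what arises without an effect. For counts of lists, the real split alone reached its count for 58 nm against control (15 against at most 12, 1 of 35 splits). The same held for 58 nm against 35 nm (18 against 14, 1 of 35). For 35 nm against control, 3 of 35 splits gave at least the 14 lists of the real one and the highest other gave 14. Over the 3 comparisons, splits that exchanged 1 library gave up to 14, 12 and 14 lists. Those that exchanged 2 libraries gave at most 2, 7 and 7. A split with 1 library exchanged keeps part of the real difference, so for lists these shares neither exclude chance nor point to it. These shares were not adjusted over the counts examined.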

How the results depend on the processing

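Removal of the gene length and GC trends, of the length trend alone, limma-voom and array weights were chosen only after the data were seen. Requiring a log2 fold change of at least 1 left 85, 20 and 19 genes (35 nm against control, 58 nm against control, 58 nm against 35 nm), by its own construction. Without the filter 252 genes passed in 58 nm against control and 723 in 58 nm against 35 nm; the cause was not tested. With single libraries left out, 3480 to 4685 genes passed for 35 nm against control, 228 (without control 3) to 560 (without 35 nm library 3) for 58 nm against control and 723 (without 58 nm library 4) to 2324 (without 58 nm library 1) for 58 nm against 35 nm. With an estimated correlation 0, 0 and 2 lists were called, and fry called 25 in 35 nm against control, where it tests each list by itself. Some lists lost their call although their estimated correlation lay below the preset 0.01, such as metallothioneins in 58 nm against control (-0.0054). Genes moving together therefore do not account for every lost call. In 58 nm against control, fry ended the calls of the NF-kB, ribosomal protein and oxidative phosphorylation lists (fry adjusted p = 0.279, 0.119 and 0.0788). In 58 nm against 35 nm it ended that of ribosomal proteins (0.0832). Lists called without single libraries numbered 13 to 17, 12 to 17 and 15 to 19. Mean list scores per library were fully separated in 23, 10 and 17 of 34 lists (smallest adjusted exact permutation p = 0.0423, 0.0972 and 0.0572). In 58 nm against control, 6 called lists were not separated (adjusted p = 0.162 to 0.309). They were ribosomal proteins, oxidative phosphorylation, NF-kB, immediate early, metallothionein and basement membrane genes.

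Quantile normalization reversed HMGCS1 for 35 nm against control (-0.031) and B2M for 58 nm against 35 nm (0.132); the cause was not tested. Of 281 gene results, that setting left 255 the same and weakened 16. Leaving out single libraries kept 226 gene results and 84 of 102 list results on their side of the threshold. Removal of both trends kept 262 and 90, array weights 268 and 98, limma-voom 265 and 99, upper-quartile rescaling 269 and 96, the unfiltered fit 252 and 94, limma without trend and robust prior 270 and 100, and a pseudocount of 0.1 kept 280 and 102. A fit of the 8 libraries compared kept 262 and 101, removal of the length trend alone 273 and 92, and a filter at 5 FPKM 235 of 245 and 80 of 90. These gene results cover the named genes, many of them picked for large changes. Over all genes, removal of both trends kept 2504 of 4315 calls in the same direction for 35 nm against control. It kept 383 of 503 for 58 nm against control and 995 of 1382 for 58 nm against 35 nm. The correlation of fold changes between both sizes (0.675, jackknife SE 0.0957) moved by less than its error in each setting. That error was itself taken over the fits with 1 library left out, among which r was lowest, at 0.584, without 58 nm library 1.

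Libraries share replicate numbers across groups, but nothing in the labels pairs them. Deviations of libraries with the same number correlated at -0.065 to 0.159, with 1 of 12 pairs above 0.1, and 0, 0 and 2 of 4 libraries were closest to their own number in the 3 comparisons, so not every library was. With the replicate number as a block 4187, 453 and 1272 genes and 14, 15 and 18 lists were called. Of the calls without the block, 4007 of 4315, 390 of 503 and 1154 of 1382 stayed in the same direction. The block left 268 of 281 gene results on their side of the threshold, weakened 9 and strengthened 4. Depth limits genes with few reads, such as MIR590 with means of 12 against 3.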

Other observations

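The comparison of the interferon list with other lists was chosen only after its result was seen, and so were the genes named here. The protease inhibitor TIMP3 fell from 309 ± 16.2 FPKM in controls to 190 ± 9.13 at 35 nm and 204 ± 22.7 at 58 nm (adjusted p = 1.65e-05 and 0.000229; 58 nm against 35 nm 0.418), while its relative TIMP2 fell at 35 nm alone (131 to 96.0 FPKM, adjusted p = 1.89e-06) and differed between both sizes (adjusted p = 1.85e-05). The matrix protein TNC rose by 1.11 at 35 nm and 0.44 at 58 nm on the log2 scale (adjusted p = 1.01e-07 and 0.000678). The smooth muscle gene TAGLN rose by 0.75 and 0.38 (adjusted p = 1.44e-05 and 0.0133, the latter 0.0505 without control 3). The differentiation regulators ID2 and SOX9 fell by 0.59 and 0.67 at 35 nm (adjusted p = 0.000782 and 0.000251). TXNIP, which restrains glucose uptake, fell by 0.62 and 0.29 (adjusted p = 1.23e-06 and 0.00325), and TFRC and ACO1, of iron uptake and sensing, rose in both treated groups (35 nm adjusted p = 1.94e-07 and 1.23e-06, 58 nm adjusted p = 0.000185 and 0.0015). MFSD2A, a lipid transporter of brain endothelium, rose by 0.62 at 35 nm (adjusted p = 0.000435).

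Genes were also grouped into families by the stem of their symbols. Members of the lists were not removed from these families, so a family's change may repeat that of a list, which was not tested. In the PARP family, whose members modify proteins with ADP-ribose, 8 of 12 fell and 1 rose at 35 nm (median -0.37, camera adjusted p = 0.000288, adjusted p = 0.442 with an estimated correlation), and 5 of 12 fell at 58 nm (median -0.18, camera adjusted p = 1.68e-05, adjusted p = 0.186 with an estimated correlation). Mitochondrial ribosomal proteins of the large subunit rose in 22 of 49 cases and fell in 1 at 35 nm (median 0.15, camera adjusted p = 0.00284, adjusted p = 0.613 with an estimated correlation). Those of the small subunit were not called, with 10 of 29 higher and 2 lower (median 0.10, camera adjusted p = 0.0978), but were called after removal of the length and GC trends (median 0.155, adjusted p = 0.016). Families tested numbered 114. The highest members in controls of the pericyte, fibroblast, epithelial and astrocyte lists were ANPEP at 116, COL1A1 at 129, KRT7 at 70 and GJA1 at 66.7 FPKM. Other members of these lists were near 0 in controls, such as KCNJ8, EPCAM and CDH1 at 0, PDGFRA at 0.0363 and GFAP at 0.18 FPKM. These levels do not show whether other cell types were present. The highest endothelial marker, ENG, was at 103 FPKM, followed by CLEC14A at 39. CDH5, PECAM1 and VWF averaged only 1.44, 1.42 and 1.02 FPKM in controls, FLT1 0.011 and KDR 0. CD14, the highest of the leukocyte markers, was at 1.04. Of 31 endothelial markers 17 reached 1 FPKM in controls, as did 6 of 12 pericyte, 3 of 10 astrocyte, 1 of 12 leukocyte, 5 of 11 epithelial and 5 of 10 fibroblast markers.

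Whether MHC class I genes fall with the interferon list was tested on 15 genes of antigen presentation. Their median was -0.192 at 58 nm, where 4 fell (camera p = 1.07e-08, p = 0.0205 with an estimated correlation), and -0.025 at 35 nm, where 3 rose and 3 fell (camera p = 0.766). The difference between both sizes was called (p = 2.42e-06, 0.0459 with an estimated correlation), and members went both ways at 35 nm, so the hypothesis stays open. HLA-B rose from 461 to 569 FPKM at 35 nm (adjusted p = 0.00204). Its regulator NLRC5 fell by 0.39 at both sizes (adjusted p = 4.3e-05 and 0.000185).

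Whether the interferon receptor and its kinases fall with the interferon list stays open. Of IFNAR1, JAK1 and TYK2, 0 were lower past the threshold at both sizes, but the receptor chain IFNAR2 was below the filter (0.311 FPKM in controls) and could not be tested. The gene for interferon beta, IFNB1, had at most 9 reads in any library. Of the interferon ligand genes examined, only IFNE passed the filter. It fell from 1.86 to 0.909 FPKM at 35 nm (adjusted p = 0.00736) and stood at 1.49 FPKM at 58 nm (adjusted p = 0.523). The interferon list may be less sensitive to particle size than the others: the ratio of its medians, 58 nm over 35 nm, was 0.94, against at most 0.897 for another list called at 35 nm. It was the highest in 8 of 12 fits with a library left out, which leaves this open. For the mitochondrially encoded transcripts, lower nuclear genes of mitochondrial transcription and RNA stability were argued against, their median being 0.069 at 35 nm, with 6 of 15 higher and 0 lower.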
